A study of Oryza sativa with 12 samples.

How the data were processed

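DNA affinity purification sequencing (DAP-seq) measures where a transcription factor binds purified genomic DNA in a test tube. Per the labels' protocols, genomic DNA came from roots of rice (Oryza sativa, cultivar Nipponbare) colonized by the arbuscular mycorrhizal fungus Rhizophagus irregularis. Plants were supplied with 25 uM phosphate, and roots were taken 7 weeks after inoculation with colonization above 90%. The DNA was sheared to about 250 bp and made into a library. That library was incubated for 1 h with a HaloTag fusion of IDD7, or of green fluorescent protein (GFP) as the control, made in a wheat germ cell-free system. Bound fragments were amplified and sequenced as 150 bp paired reads, about 6 Gb per library.

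The series holds 12 libraries, 6 with IDD7 and 6 with GFP. The labels number the biological replicates 2, 3 and 4, and each was run as technical replicates A and B. Groups were taken from the sample titles. The authors deposited 2 peak lists for IDD7, called list A and list B here. Per the labels, each is a technical replicate that pools the 3 biological replicates, with peaks called relative to GFP.

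Per the submitters' processing notes, fastp 0.23.2, FastQC, Bowtie2, deepTools, MACS2 and bedtools were used. Their settings, the peak threshold and the genome build are not given in the sources used here. Each deposited list holds a sequence name, a start and an end, with no header. Every interval is 500 bp wide, and its midpoint was taken as the summit. The lists carry no peak height, enrichment or significance, and depth behind a peak is unknown. No interval for the strength of a peak can therefore be given. The 14 sequence names are 12 numbered chromosomes, ChrSy and ChrUn. This naming is used by the rice pseudomolecules of the MSU annotation project, but no source used here names the build. Coordinates below are 1-based, in the build of the lists.

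The reference gene table supplied here belongs to another assembly (ASM3414082v1). It lacks 2 of the 14 sequence names and holds no sequence, so none of its coordinates were used. Before the data were examined, gene lists for symbiosis, phosphate, strigolactone and gibberellin, keyword lists, and the TTTGTCG core of indeterminate domain proteins had been fixed. The rule for named genes took the best scored promoter summits overall and within those lists. Promoters, gene features, gene lists, the core sequence, enriched short sequences and peak scores were not analysed here, so no gene is named. Windows and stretches named below were chosen after their counts were seen, as the extremes of each table.

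A summit of one list was called shared when a summit of the other lay within 250 bp, which equals an overlap of at least 50% between 500 bp intervals. The same summit could be the partner of more than 1 summit of the other list. Overlap was compared by a permutation of positions, with 100 random placements of the other list, each summit kept on its sequence and placed evenly from position 1 to the last interval end in either list. These spans sum to 374.2 Mb. Gaps in the assembly and mappability were not modelled. Shared summits take the position of list A. Densities were counted in the 367 complete 1 Mb windows of the 12 chromosomes. Chromosomes were compared by permuting windows 100000 times. The recurring share by chromosome was tested both by permuting single summits and by permuting windows, which keeps neighbouring summits together. Window counts were compared by Spearman correlation, with windows rotated within each chromosome 100000 times. The extremes (longest stretch without a summit, richest and poorest window) were compared with the same extreme over the genome in 1000 random placements. In an earlier set of 100 placements that extreme had moved with the random draw. The window permutation of shares and the larger set of placements were chosen after seeing the data. So were the comparisons other than the overlap of the lists and the densities of shared, list A and list B summits by chromosome. Those densities had been planned against placement on sequence without unsequenced bases, and permuting windows replaced this after the lists were seen. The outer 5 Mb of each chromosome were compared with the rest by an exact two-sided sign-flip permutation test over the 12 chromosomes. All pairs of summits of a list within a range of gaps were counted, whether adjacent or not. These counts were compared with 100 placements that moved each summit by up to 50 kb. Shares carry 95% Wilson intervals, which cover counting error only, since summits are not independent molecules or replicates. Tests were two-sided, except the chi-square comparisons of chromosomes and the comparisons of extremes, which were one-sided. The 30 tests of the comparisons were adjusted together by the Benjamini-Hochberg method. The extremes and the tests of explanations were not adjusted. The smallest p that 100 placements can give is 0.0099.

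The statistics were tested on simulated lists of the real sizes. Of 55.0% of summits planted as shared, 55.1% were recovered after removing chance matches. Of 600 planted close pairs, 598.3 were recovered as excess. Simulated summits were drawn evenly within each 1 Mb window. The simulation therefore held no patchy sequence at finer scale and did not test its effect on close pairs. A planted interior to terminal density ratio of 1.2 was recovered as 1.19. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Alternatives were the overlap required, the random placement, the window size, the terminal stretch and each list alone.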

Results

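The series addresses where OsIDD7 binds the rice genome, in a study of arbuscular mycorrhizal symbiosis. IDD proteins are plant transcription factors with zinc fingers of the indeterminate domain. The labels give 6 libraries with IDD7 and 6 with GFP. List A held 27495 summits and list B held 24744, each from 3 pooled biological replicates. Of these, 27464 and 24718 lay on the 12 numbered chromosomes. The 500 bp intervals covered 3.67% of the spanned sequence in list A and 3.30% in list B. Within a list, neighbouring summits were a median of 8150 bp apart in list A and 9080 bp in list B. The GFP control enters these lists through the authors' peak calling, and its own signal was not analysed here. A comparison of list A with list B measures repeatability between technical pools, not between plants. Where summits are called IDD7 sites below, background calls present in both pools were not separated from IDD7 binding.

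The first comparison asked which IDD7 sites were called in both technical pools. IDD7 summits recurred at 15606 positions of list A, which is 56.8% of that list (95% Wilson interval 56.2 to 57.3%). In list B 15607 summits had a partner, or 63.1% (62.5 to 63.7%). List A had 11889 summits without a partner and list B had 9137. List A summits and unmatched list B summits together made 36632 positions, of which 42.6% were in both lists. Positions whose intervals overlap by less than 50% were counted separately, so they are not all distinct regions. When list B was placed at random, a mean of 3.26% and at most 3.52% of list A summits had a partner, so the observed share was 17.4 times chance (permutation p = 0.0099 over 100 random placements, the smallest they can give; adjusted p = 0.0162). Whether both lists were called against the same GFP libraries is not given in the sources used here, and random placement does not model a control common to both. The fold depends on the distance allowed. It was 9.17 for any overlap of the intervals, where 58.9% of list A was shared, and 72.3 for an overlap of at least 90%, where 48.0% was shared.

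Shared sites were placed at nearly the same base in both pools. The median distance between partner summits was 16 bp, and the middle quartiles ran from 6 to 34 bp. Of the shared summits, 38.1% lay within 10 bp of their partner, 84.7% within 50 bp, 14824 of 15606 lay within 100 bp, and 376 lay at the identical position. The mean signed distance was -0.66 bp (B minus A, SD 45.5, n = 15606 summits), with 7578 partners to the right and 7652 to the left. The test of this mean against 0 did not pass the threshold (sign-flip permutation p = 0.069).

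**Figure D1:**
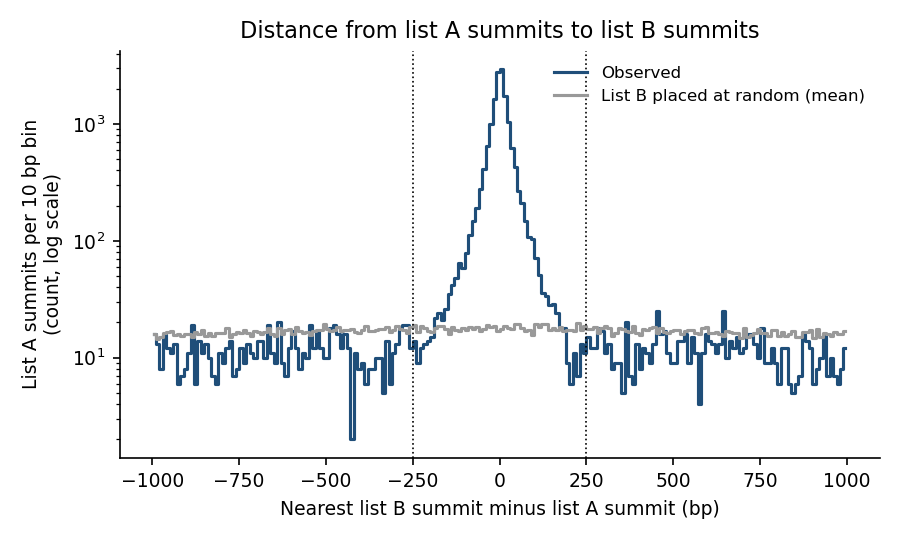
Number of list A summits per 10 bp bin (y axis, log scale) by the signed distance in bp to the nearest list B summit (x axis), observed (blue) and as the mean of 20 random placements of list B (grey). Dotted lines mark 250 bp on either side, and the observed peak is narrow, with a median absolute distance of 16 bp among shared summits.

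The next comparison asked how sites were spread over the chromosomes. Shared IDD7 sites occurred on every numbered chromosome at similar density, with a mean of 41.6 per Mb (SD 2.01, n = 12 chromosomes). Chromosome 4 had the highest density, 45.3 per Mb (1607 shared summits), followed by chromosome 3 with 45.2 per Mb (1645). Chromosome 5 had the lowest, 39.5 per Mb (1183). The differences between chromosomes did not exceed the spread between 1 Mb windows (chi-square 35.1, permutation p = 0.133, adjusted p = 0.166). List A alone gave the same outcome (chi-square 24.6, permutation p = 0.566), whereas list B alone passed the test (chi-square 58.8, permutation p = 0.0057, adjusted p = 0.0162). Densities in list B ran from 61.8 per Mb on chromosome 12 to 71.8 per Mb on chromosome 3. Summits in list B only differed between chromosomes, from 21.9 per Mb on chromosome 6 to 27.8 per Mb on chromosome 2 (chi-square 48.2, permutation p = 2.2e-04, adjusted p = 0.0015). Those in list A only did not pass the test (30.7 to 32.9 per Mb, chi-square 4.31, permutation p = 0.993). Permuting windows treats them as exchangeable, whereas neighbouring windows resembled one another for shared summits (Spearman rho = 0.27). The p of these chromosome tests may therefore be too small.

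The share of sites that recurred also varied little by chromosome. In list A it ran from 55.0% on chromosome 5 to 58.8% on chromosome 3, which did not pass the test (permutation p = 0.209 over summits and 0.290 over windows). In list B it ran from 60.6% on chromosome 2 to 66.3% on chromosome 4. This passed when single summits were permuted (permutation p = 0.0066, adjusted p = 0.0162) and not when 1 Mb windows were permuted (permutation p = 0.072, adjusted p = 0.094). On ChrSy, list A had 24 summits and list B had 16, and 13 list A summits were shared. On ChrUn the counts were 7 and 10, with 6 list A summits shared. Shared density was 22.1 per Mb on ChrSy and 9.59 per Mb on ChrUn, below that of all 12 numbered chromosomes, from counts too small for a firm comparison.

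Within chromosomes, shared sites were unevenly spread. A 1 Mb window held a median of 41 shared summits, with the middle quartiles from 35 to 48. The densest window, on chromosome 2 from 27000001 to 28000000, held 70 shared summits, with 103 summits in each list. The window on chromosome 4 from 10000001 to 11000000 held 69. Chromosome 6 from 15000001 to 16000000 held 68, and chromosome 3 from 20000001 to 21000000 held 67. The sparsest windows held 18 each and lay on chromosome 12 from 20000001 to 21000000 and on chromosome 8 from 3000001 to 4000000. The first window of chromosome 2 held 22. The variance of window counts was 2.17 times their mean, against 1.06 on average and 1.24 at most in 100 random placements (permutation p = 0.0099, adjusted p = 0.0162). The densest window of 1000 random placements had a median of 63 shared summits, and 70 or more was rare (permutation p = 0.029). The sparsest had a median of 24 (permutation p = 0.019 for 18 or fewer). Neighbouring windows resembled one another (Pearson r = 0.27 and Spearman rho = 0.27 across 355 neighbouring pairs of windows, which are not independent replicates).

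At finer scale, a 100 kb window held a mean of 4.18 shared summits, and 129 of 3726 windows (3.46%) held none. The richest lay on chromosome 4 from 10600001 to 10700000, with 18 shared summits among 21 in list A and 22 in list B. The richest window of a random placement had a median of 13 (permutation p = 0.0020 for 18 or more, over 1000 placements). Chromosome 3 from 18000001 to 18100000 held 16, and chromosome 11 from 11400001 to 11500000 held 15. Counts of list A and list B differed at an unadjusted p under 0.05 in 4 of these windows and at an adjusted p under 0.05 in 0 (exact binomial test with Benjamini-Hochberg adjustment over the windows). Shared summits enter both counts, and counts per window are small. The test therefore had little room to pass, and its outcome does not measure local agreement of the lists.

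Some long stretches carried no IDD7 site in either list. The longest spanned 354.5 kb of chromosome 12, from 20433037 to 20787558. It lay inside a 1 Mb window that tied for the lowest shared count. Next came 166.3 kb on chromosome 2 from 13603843 to 13770134. Chromosome 10 had 160.7 kb from 10781128 to 10941866, and chromosome 11 had 158.1 kb from 12336348 to 12494457. The longest stretch of a random placement had a median of 111.0 kb. Of 1000 placements, 0 held a stretch as long as that on chromosome 12 (permutation p = 0.0010, the smallest they can give), and 4 held one as long as that on chromosome 2 (permutation p = 0.0050). Unsequenced bases and unmappable repeats in these stretches were not examined.

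**Figure D2:**
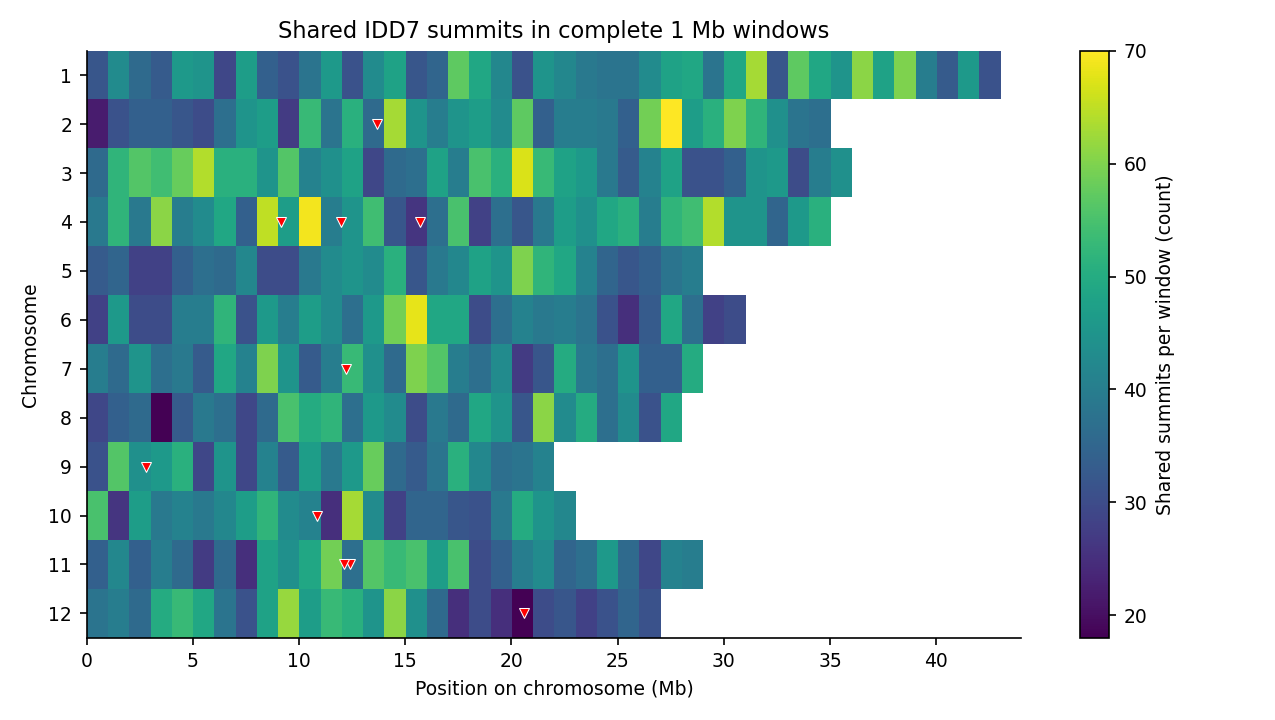
Shared summits in each complete 1 Mb window (colour, count) by position in Mb (x axis) on chromosomes 1 to 12 (y axis). Red triangles mark the 10 longest stretches without a summit in either list, and counts run from 18 to 70 per window.

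Shared sites were sparser in the outer 5 Mb of the chromosomes than in the interior. In the outer 5 Mb the shared density was 39.1 per Mb (SD 3.79, n = 12 chromosomes), against 42.7 per Mb (SD 1.73) in the interior. The interior was denser by 3.70 summits per Mb, a ratio of 1.09, and was higher on 9 of 12 chromosomes (exact sign-flip permutation p = 0.0073, adjusted p = 0.0162). Chromosomes 2 and 8 had the largest ratios, both 1.24, and chromosome 5 had 1.21. Chromosomes 3, 9 and 10 had ratios of 0.98, 0.97 and 0.99. Leaving out any 1 chromosome kept the exact p between 0.0068 and 0.0146. Summits in list A only had 31.1 per Mb at the ends and 32.0 in the interior (exact p = 0.388). Summits in list B only had 24.1 and 24.6 per Mb (exact p = 0.371). The comparison of ends with interior was chosen after the windows were seen.

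**Figure D3:**
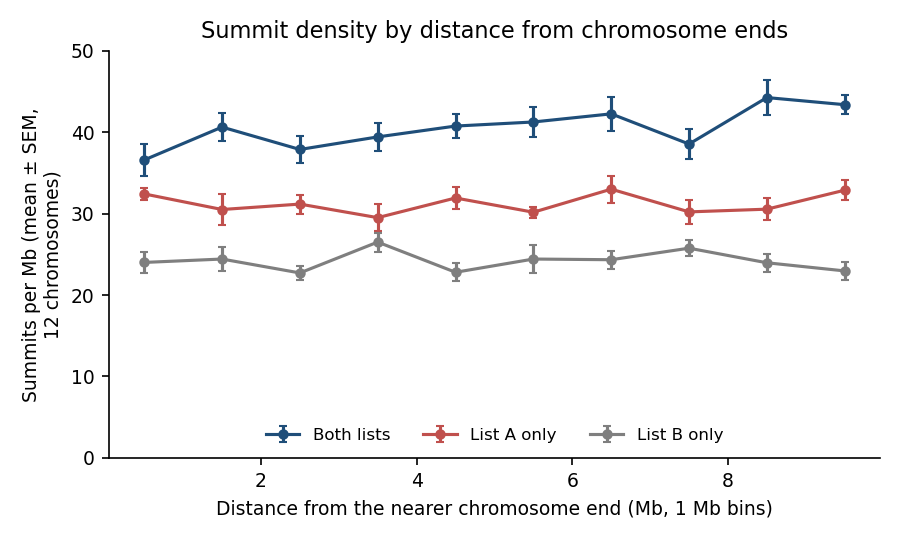
Summits per Mb (y axis, mean with SEM over the 12 chromosomes) by distance in Mb from the nearer chromosome end (x axis, 1 Mb bins), for summits in both lists and in 1 list only. Shared density is 36.6 per Mb in the outermost bin and 43.4 per Mb in the bin from 9 to 10 Mb, with no steady rise between them (40.6 from 1 to 2 Mb and 38.5 from 7 to 8 Mb).

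The last comparison asked whether sites occurred near one another. Called summits lay 500 to 10000 bp apart more often than after local random placement. That placement did not model assembly gaps or mappability. Grouping of IDD7 binding sites can therefore not be separated from patchy mappable sequence. Pairs of shared summits 500 to 1000 bp apart numbered 571, or 1.62 times the mean of 351.4 after moving each summit by up to 50 kb. The ratio was 1.36 for gaps of 1000 to 2000 bp, 1.28 for 2000 to 5000 bp and 1.11 for 5000 to 10000 bp. For the shortest of these gaps, list A had 1693 pairs (ratio 1.57) and list B had 1291 pairs (ratio 1.47). All 3 ratios at 500 to 1000 bp exceeded every one of 100 placements (permutation p = 0.0099, adjusted p = 0.0162). These pairs were examined after the lists were seen. Pairs under 500 bp apart were left out of the ratios. They numbered 277 in list A and 238 in list B, below the random means of 1081.1 and 877.0 at 500 to 1000 bp. No random placement was counted for their own range, so the excess holds only for gaps of 500 bp or more. Summits under 500 bp from a neighbour recurred less often than all others together. In list A 47.3% of 550 such summits were shared (95% Wilson interval 43.1 to 51.4%), against 57.0% of the rest (Fisher's exact test, p = 7.13e-06). In list B the shares were 52.1% of 474 and 63.3% (Fisher's exact test, p = 8.76e-07). The close summits are members of 277 pairs in list A and 238 in list B. Both tests treat the members of a pair as independent, so their p may be too small. Of summits at least 20000 bp from a neighbour, 52.6% of 1440 were shared in list A (95% Wilson interval 50.1 to 55.2%) and 61.5% of 1683 in list B (59.1 to 63.8%), and these were not tested against other distances.

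**Figure D4:**
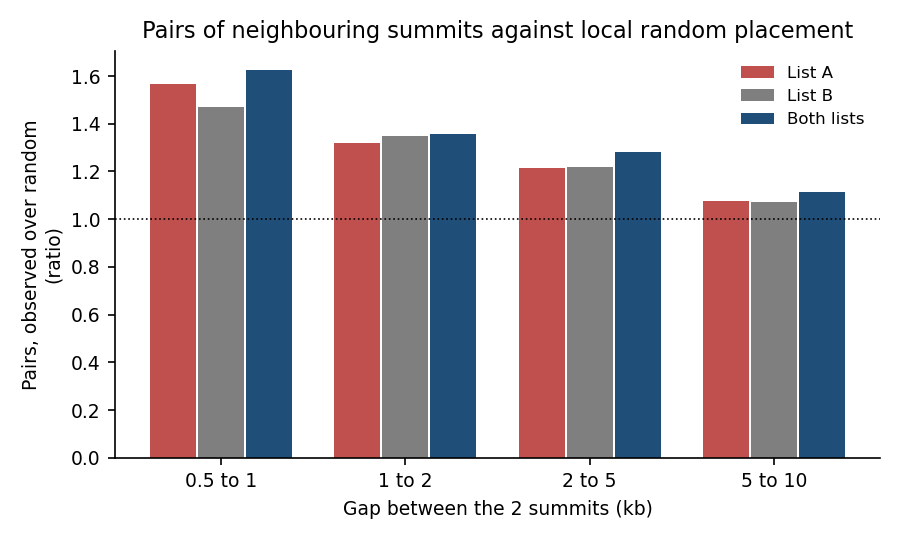
Ratio of observed pairs of summits to the mean of 100 local random placements (y axis, bars from 0) by the gap between the 2 summits in kb (x axis), for list A, list B and shared summits. The ratio for shared summits falls from 1.62 at 0.5 to 1 kb to 1.11 at 5 to 10 kb, and the dotted line marks 1. Gaps under 0.5 kb are not shown.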

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

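The test of this difference was chosen after the densities by chromosome were seen. Sites called in 1 pool only were divided between pools A and B in unequal proportions across the chromosomes, and this difference between the pools drew attention (chi-square 26.6 over 12 chromosomes, permutation p = 0.0146, adjusted p = 0.0219). Chromosome 2 had 31.6 list A only and 27.8 list B only summits per Mb, whereas chromosome 6 had 32.2 and 21.9. Taken alone, list B only summits differed between chromosomes (21.9 to 27.8 per Mb, chi-square 48.2, permutation p = 2.2e-04, adjusted p = 0.0015), and list A only summits did not pass the test (30.7 to 32.9 per Mb, chi-square 4.31, permutation p = 0.993).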

How the results depend on the processing

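In the 21 alternatives computed, 20 kept the direction and the side of the threshold and 0 reversed. The overlap requirement and the placement within 50 kb (15.1 times chance) were planned; the other 16 alternatives were chosen after seeing the data, although a comparison of chromosomes within each list had been planned as a test. The exception was the comparison of chromosomes, which did not pass for shared summits and passed for list B alone (chi-square 58.8). The summits in list B only, which are part of that list, also differed between chromosomes (chi-square 48.2, permutation p = 2.2e-04); the cause was not tested. The ratio of interior to terminal density lay between 1.07 and 1.10. Pairs 500 to 1000 bp apart lay between 1.47 and 1.67 times chance. The correlation of list A only with list B only counts lay between 0.13 and 0.25. Of the 31 alternatives planned, 28 were not run, because they need peak scores, sequence or gene positions. No biological replicate could be left out, because each list pools 3. No paired analysis was possible because the replicate numbers belong to libraries pooled within each list, and the lists carry no value per library. Without depth or peak height, a site missing from 1 list cannot be separated from one just under the threshold.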

Other observations

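The tests in this part, apart from that of close pairs, were chosen after the result was seen. Counts of sites called in 1 pool only rose weakly with those of shared sites. Across the 367 windows of 1 Mb, list A only counts correlated with shared counts (Spearman rho = 0.37, Pearson r = 0.38, rotation permutation p = 1.0e-05, the smallest the rotations can give; adjusted p = 1.0e-04). List A only and list B only counts, which have no summit in common, also correlated (rho = 0.18, r = 0.21, rotation permutation p = 0.00061, adjusted p = 0.0030). Windows are not independent replicates.

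Why 43.2% of list A and 36.9% of list B had no partner was weighed first. Placement of the summit of 1 site more than 250 bp apart is argued against, since 5.01% of list A only and 6.36% of list B only summits had a summit of the other list more than 250 and less than 500 bp away. Calls scattered evenly along the chromosomes are argued against by the list A only counts, whose variance was 1.49 times their mean against at most 1.14 in 100 random placements. They are argued against for list B by the correlation of its unmatched counts with shared counts (rho = 0.22, rotation permutation p = 0.00025). Weak IDD7 sites near the calling threshold and background that follows mappable sequence stay open, and no biological explanation was tested, since both lists belong to IDD7.

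The lower density of shared sites near chromosome ends was weighed next. A loss of mappable sequence that scales all calls alike predicts equal ratios of interior to terminal density for shared and unmatched summits. The mean log2 ratio was 0.14 for shared summits (SD 0.13) and 0.04 for those in 1 list only (SD 0.11, n = 12 chromosomes), and the exact sign-flip permutation p of the difference was 0.018, with a larger ratio for shared summits on 9 chromosomes. A loss that scales all calls alike is therefore argued against as the only cause. The test cannot decide on poorer mappability that lowers the chance of a call in each list separately. Such a loss would lower shared summits more than unmatched ones, so it stays open. Copy number, base composition and gene density also stay open, and no biological explanation was tested.

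The lower recurrence of summits under 500 bp apart was weighed last. A site called as 2 summits in 1 list and 1 in the other predicts more pairs with exactly 1 member repeated, where the single summit lies near only 1 of the 2. A single summit between them, within 250 bp of each, makes both repeated, and the count below misses that case. Pairs with exactly 1 member repeated made up 53.4% of 277 in list A, against 47.4% of pairs 750 to 1500 bp apart (Fisher's exact test, p = 0.064), and 54.2% of 238 in list B against 41.9% (Fisher's exact test, p = 0.000466). Pairs with neither member repeated were also more frequent, 72 of 277 against 372 of 2150 in list A (Fisher's exact test, p = 0.000685) and 20.6% against 13.3% in list B (Fisher's exact test, p = 0.0039), which this explanation does not predict. No biological explanation was tested, and this one stays open, because list A missed the threshold and a lower recurrence by itself moves the share with exactly 1 repeated.

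A hypothesis was that the long stretches without a site lie in sparse regions. The 1 Mb on either side of the 10 longest stretches held 46.4 shared summits per Mb (SD 10.6), against 42.4 for the same chromosomes, and 7 of the 10 had flanks above their chromosome's density (permutation p = 0.096). The stretch on chromosome 4 from 9072304 to 9225652 had 62 per Mb in its flanks, and that on chromosome 12 from 20433037 to 20787558 had 29.5. The stretches on chromosome 11, from 12054383 to 12198216 and from 12336348 to 12494457, lie within 1 Mb of one another. Their flanks overlap, so the 10 values are not independent. The test decides neither way, and a missing or repetitive reference sequence in these stretches was not examined.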
